A study of Rattus norvegicus with 21 samples.

How the data were processed

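RNA from the dentate gyrus, the hippocampal subfield that holds granule neurons, was measured on Affymetrix rat Gene ST arrays in 18 male Wistar rats, 3 in each of 6 groups. One group was untreated (control), 1 went through 6 weeks of unpredictable chronic mild stress, and 4 went through the same stress and received an antidepressant by daily injection in the last 2 weeks. The drugs were fluoxetine, imipramine and tianeptine at 10 mg/kg and agomelatine at 40 mg/kg, so the doses were not matched across all 4, and per the labels' protocols the vehicle differed between drugs (water, saline or hydroxyethylcellulose). The labels' protocols describe injections for the drug groups only and do not say whether control and stressed animals were injected, so a difference between a drug and stress alone cannot be separated from an effect of daily injection. Per the labels' protocols the RNA was column-purified with a DNase step and biotin-labelled cDNA was hybridised. Each of the 3 control animals was also run on a repeat array, which gives 21 arrays for 18 animals.

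The deposited values are log2 expression values per probe set, made by the authors with RMA in Affymetrix Expression Console 1.2, per the submitters' processing notes. RMA subtracts background, quantile-normalises the arrays and summarises the probes of a probe set, and small differences tend to be shrunk at low signal. The values ran from 3.57 to 14.4 and the array medians from 7.99 to 8.10, and over the tested genes the array medians ran from 9.18 to 9.35, so part of the array-wide differences remained. Arrays give no read depth, and the precision is limited by the number of animals. The date or round in which an array was run is not given in the sources used here.

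The platform annotation supplied for the 29214 probe sets gave 1 gene symbol for 15310 of them and several for 323, and 13581 were unnamed here. Of the probe sets with 1 symbol, 15279 matched the RefSeq gene table of assembly GRCr8 by gene number, which was used for names only, and no coordinates are printed because the array's genome build is not given in the sources used here. Probe sets with 1 symbol (14506 genes) were kept when their mean over the animals was at or above the 25th percentile, a log2 value of 7.165, and the probe set with the highest mean stood for each gene, leaving 10804 genes. Among the 424 genes with more than 1 probe set above that level, none had probe sets called in opposite directions in the 5 comparisons of stress with control and of each drug with stress. Only agomelatine against stress had called genes in the main fit, so the check bears on that comparison. It does not count genes with 1 probe set called and another not. Among all probe sets, 319 shared all their values with another probe set, and none of the tested genes did.

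The 2 arrays of a control animal were averaged, giving 1 value per animal. limma 3.58.1 in R 4.3.3 fitted 1 mean per group over all 18 animals (12 residual degrees of freedom), with moderated variances that followed the mean expression (eBayes with trend). Each of the 15 pairwise comparisons of groups was adjusted over the 10804 genes by the Benjamini-Hochberg method, and a gene is said to have risen, fallen or changed at an adjusted p under 0.05. A moderated F test asked which genes differed among the 6 groups. Fold changes are differences of mean log2 values, given with their standard errors. Values of single genes and lists in a group are means ± SD over 3 animals.

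Of 31 gene lists, 30 had at least 5 measured members and were tested (19 pathway and 11 cell type or quality lists). The list of blood cell genes had 1 measured member and was not tested. limma's camera with a preset correlation of 0.01 compared each list with all other genes, adjusted over the lists, and the same test with an estimated correlation and limma's fry, which tests whether the members move 1 way on balance, were run beside it. All adjusted p-values below come from these limma tests. A list score is the mean over its members of each animal's log2 value minus the gene's mean over the animals.

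The groups, tests, filters, gene lists, naming rule and most alternatives were fixed before the data were examined. The rule named, for stress against control and each drug against stress, the 12 highest and 12 lowest fold changes among called genes whose animals did not overlap between the groups. Where a direction had under 10 such genes it was filled to 10 with the smallest p among genes without overlap. For the other comparisons 3 genes per direction were taken. A fixed panel of 19 genes and up to 4 members of each called list were added, and only part of the resulting names is printed. Panel genes Mki67 and Mtnr1a were not among the tested genes. Gpr17, Fkbp4 and Cldn5 with imipramine, and Nr4a1, Nr4a2, Homer1, Idi1 and Insig1 in agomelatine against control, fall outside the rule and were chosen after their values were seen.

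Alternatives covered the choice of control arrays, all 21 arrays with animal as a random block (statmod 1.5.0), the low signal filter, all probe sets, renewed scaling, the variance prior, array weights, the replicate number as a block, a threshold of 0.1, fits on the 2 groups compared and leaving out each animal. A further alternative added as covariate each animal's position along the mean difference between the repeat and first arrays of the control animals. In addition 3 alternatives were added after seeing the data: leaving out the agomelatine group, and the choroid plexus or the oligodendrocyte list score as a covariate. The replicate numbers were not treated as pairs, since in no comparison did all same-numbered animals correlate at over 0.1. Tables were read with the R package data.table, version 1.17.8.

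The steps were tested on simulated data with the real gene means and variances, in which 200 of 10804 genes were changed by a log2 difference of 0.5 or 1. For stress against control 97% of the genes changed by 0.5 and 99% of those changed by 1 were recovered, with 12 false calls. The corresponding shares for changes of 0.5 were 91% for fluoxetine, 90% for imipramine, 91% for tianeptine and 90% for agomelatine against stress. A shift of 0.2 put into the glucocorticoid-responsive list was recovered in each of these 5 comparisons, with the preset and with the estimated correlation, and 1 other list was called in the agomelatine simulation. The simulated genes vary independently of each other, unlike genes in tissue, and have the same spread in all groups. With fewer changed genes the Benjamini-Hochberg bound is stricter, so these shares do not apply where few genes changed. A count of 0 calls therefore does not show that no gene changed by 0.5.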

Results

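Gene expression in the dentate gyrus was measured in 18 rats, 3 untreated, 3 exposed to 6 weeks of unpredictable mild stress, and 3 each exposed to that stress with fluoxetine, imipramine, tianeptine or agomelatine in the last 2 weeks. Fluoxetine is a serotonin reuptake inhibitor, imipramine a tricyclic inhibitor of monoamine reuptake, tianeptine an atypical tricyclic antidepressant, and agomelatine a melatonin receptor agonist that also blocks the serotonin receptor 5-HT2C. Of 10804 genes, 730 differed among the 6 groups by the F test (2587 at an unadjusted p under 0.05), which does not say which group differed. Animals of the agomelatine group varied more among themselves, with a median SD between animals of 0.11 against 0.063 to 0.085 in the other groups. The fit takes 1 spread per gene for all groups. Standard errors may therefore be too small in comparisons with agomelatine and too large in the others. Without agomelatine 1 the count of the F test was 251, and without agomelatine 2 it was 404. It was 486 with all 21 arrays and animal as a random block, 1127 with all probe sets, 1271 at an adjusted p under 0.1, and 227, 261 and 0 with the position along the difference between repeat and first arrays (the array difference), the choroid plexus score and the oligodendrocyte score as covariates. The oligodendrocyte score itself separates the agomelatine animals (0.355 to 0.652) from all others (up to 0.0451). As a covariate it nearly stands in for that group, so the fall to 0 shows no cause.

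The repeat arrays of the 3 control animals, named technical replicates in the labels, show how far 2 arrays of the same animal differed. Rpl39, which encodes a ribosomal protein, was higher by 0.73 on the repeat arrays and H1f4, a linker histone gene, by 0.52, each at an adjusted p of 0.108. limma called 0 genes, with 2330 at an unadjusted p under 0.05 (700 higher, 1630 lower on the repeat arrays), and with the low signal filter at the 50th percentile it called 821. The median SD between the arrays of 1 animal was 0.096, which takes in any shift common to the repeat arrays. It is not a like measure of the 0.083 between control animals on the first arrays, which leaves such a shift out. Deviations of the same animal from the mean correlated at 0.294 to 0.556 between first and repeat arrays. In 4870 genes (45%, with 25% given by chance) all 3 repeat arrays lay on the same side of the first ones, so the difference between arrays had a shared part. Across genes that shared part correlated with the fold changes of agomelatine against stress (r = 0.476, no arrays in common) more than with those of the other drugs against stress (0.132 to 0.141), and genes are not independent replicates.

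Stressed and untreated animals were compared for the effect of the stress itself. Glucocorticoid-responsive genes, which the corticosteroid receptors induce, lay higher in stressed animals, with 14 of 17 members above 0 and a median log2 difference of 0.14. Dusp1, a phosphatase that inactivates MAP kinases, had a level of 9.79 ± 0.11 in stressed and 9.29 ± 0.06 in control animals (SD, n = 3), a difference of 0.50 ± 0.11 (SE). Ddit4, an inhibitor of mTORC1 signalling, differed by 0.29 ± 0.08, Nfkbia, which encodes an NF-kB inhibitor, by 0.27 ± 0.07, and Sgk1, a kinase induced by serum and glucocorticoids, by 0.25 ± 0.07. Activity-regulated genes had 21 of 28 members above 0 and a median of 0.063. Among them were Nr4a1, an orphan nuclear receptor gene (0.47 ± 0.13), Dusp6 (0.39 ± 0.12), Arc (0.34 ± 0.14) and Egr1 (0.22 ± 0.09). Interneuron and neuropeptide genes had 13 of 14 members above 0 (median 0.14), with somatostatin, Sst, at 0.26 ± 0.13, and astrocyte genes 10 of 12 (median 0.095), with the intermediate filament gene Gfap at 0.25 ± 0.13. On the lower side Marco, a scavenger receptor gene, was at -0.39 ± 0.09 and the mineralocorticoid receptor gene Nr3c2 at -0.20 ± 0.06. Rpl39 was at -0.27 ± 0.06 and H1f4 at -0.25 ± 0.05, values that depended on the control arrays, with 0.10 and 0.005 against the first arrays alone and -0.64 and -0.51 against the repeat arrays alone.

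None of these genes passed the test in stress against control: limma called 0 of 10804 genes, the smallest adjusted p was 0.728, and 583 genes had an unadjusted p under 0.05 (381 higher, 202 lower) where chance gives 540.2. The groups did not overlap in 13.1% of genes, and chance gives 10%. The genes that passed when adjusted over the list alone were 4 glucocorticoid-responsive genes (Dusp1, Sgk1, Nfkbia and Ddit4), 3 activity-regulated genes (Dusp1, Nr4a1 and Dusp6), and none of the interneuron, astrocyte or olfactory receptor genes. Of lists that were not called, Nr3c2, Gpr17 (0.25), Rpl39 and, in the inflammation list, Nfkbia passed in this way. Here and below, adjustment over the list alone was repeated for each list and comparison without a correction across them. Genes that pass only in this way may therefore do so by chance and are not counted as changed. The value of Rpl39 also depended on the control arrays, with 0.10 against the first arrays alone. By camera 5 lists passed, and by fry 0. The glucocorticoid-responsive list had a camera adjusted p of 0.000805 (adjusted p = 0.598 with an estimated correlation). The activity, interneuron and astrocyte lists each had 0.0251 (adjusted p = 0.764 with an estimated correlation). Olfactory receptor genes, dim probe sets kept for comparison, lay lower (45 of 63 below 0, median -0.046, adjusted p = 0.000805, and adjusted p = 0.897 with an estimated correlation). That a comparison list passed at the adjusted p of the glucocorticoid-responsive list limits what camera calls with the preset correlation show. In fluoxetine, imipramine and tianeptine against stress the olfactory receptor list was called as well. The nearest of the other 25 lists was that of immature neurons (0.117). The glucocorticoid-responsive call held with each animal left out, and the other 4 ended without some animal. The interneuron call ended without stress 3 (mean 0.0659, against 0.136 with all animals, adjusted p = 0.383) or control 2 (0.0834, adjusted p = 0.478). In that list stress 3 scored 0.197, the other stressed animals -0.0229 and -0.00457, and control 2 -0.185. The activity call ended without stress 1 (adjusted p = 0.0991), stress 3 (0.121), control 1 (0.124) or control 2 (0.343), the mean of 0.103 being 0.0662 without stress 3. The astrocyte call ended without stress 1 (0.0747), control 2 (0.0607) or control 3 (0.206), and that of olfactory receptors without control 1 (0.237, mean -0.0195 against -0.0496, and -0.0812 without control 2). With equal array medians, which left their signs as they were, the list medians were 0.0831 for glucocorticoid-responsive, 0.00975 for activity, 0.09 for interneuron and 0.041 for astrocyte genes and -0.0994 for olfactory receptors, the last at -0.0104 with quantile normalisation once more. Without control 1 the count of lists was 3 and without control 2 it was 2. With the repeat arrays alone as controls, 126 genes and 1 list, the glucocorticoid-responsive one, passed, and with the low signal filter at the 50th percentile 1 list did.

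Of the 17 panel genes, 0 passed in stress against control. The transthyretin gene Ttr, a marker of choroid plexus epithelium, had a difference of 1.67 ± 1.23 that came from stress 1 (11.77, against 7.13 and 8.27 in the other stressed animals). The choroid plexus list score was 0.586 in stress 1 and the meningeal score 0.608. Bdnf, the neurotrophin gene, was at 0.05 ± 0.12 and the glucocorticoid receptor gene Nr3c1 at -0.01 ± 0.06.

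**Figure D1:**
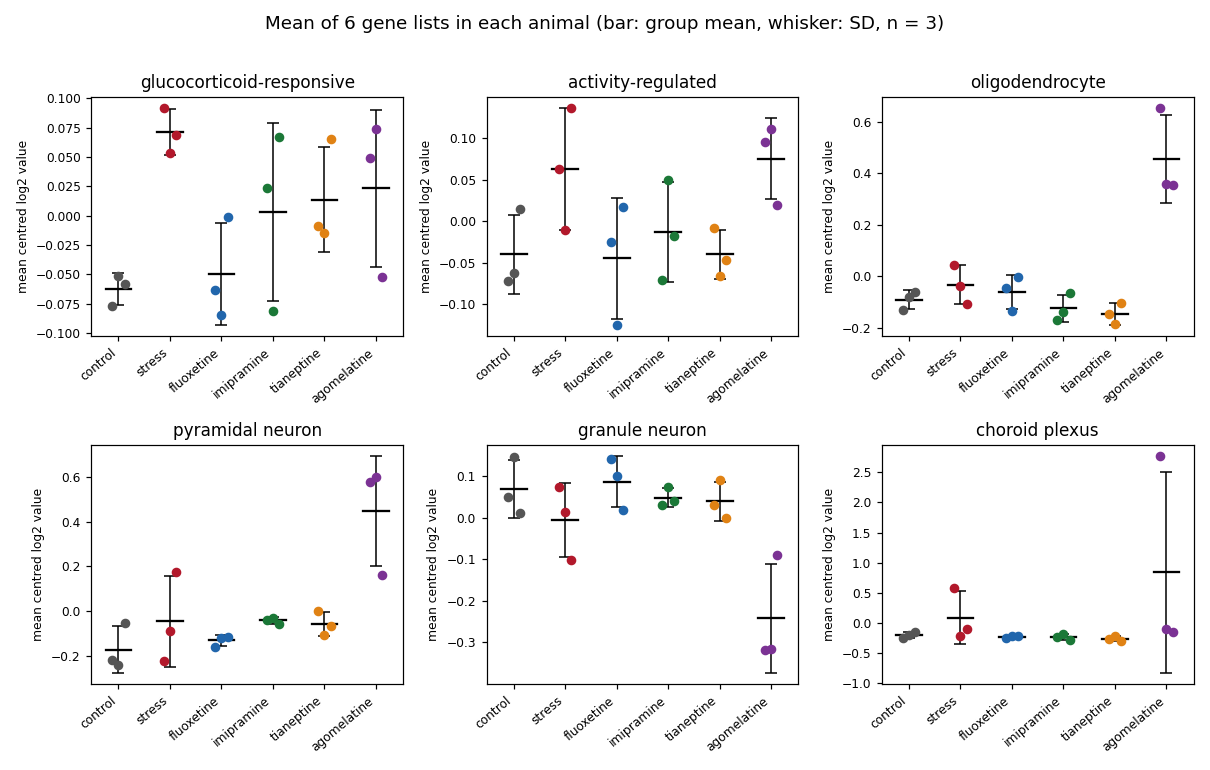
Each point is 1 animal's mean log2 value over a gene list, centred per gene over the 18 animals, by group, with the group mean (bar) and SD (whisker, n = 3). Scores of the glucocorticoid-responsive list lie between 0.053 and 0.0916 in stressed animals and below -0.05 in control animals, and the oligodendrocyte score is 0.652, 0.357 and 0.355 in the agomelatine animals.

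Fluoxetine was compared with stress alone. The same stressed animals enter stress against control and each drug against stress, so opposite values in these comparisons are not independent. Of the glucocorticoid-responsive genes 13 of 17 were below 0 (median -0.030), and of the activity-regulated genes 21 of 28 (median -0.078). Dusp1 was at 9.22 ± 0.23 against 9.79 ± 0.11 (SD, n = 3), a difference of -0.57 ± 0.11 (SE), Nfkbia at -0.35 ± 0.07, Ddit4 at -0.30 ± 0.08 and Gadd45b, a gene of activity-induced DNA repair and demethylation, at -0.29 ± 0.08. Cholesterol synthesis genes were below 0 in 15 of 17 members (median -0.082), with Acat2 at -0.26 ± 0.08 and squalene synthase, Fdft1, at -0.24 ± 0.09. Genes of endothelial cells and pericytes were below 0 in 14 of 16 (median -0.18), with the tight junction gene Cldn5 at -0.25 ± 0.08, the transporter gene Slco1a4 at -0.31 ± 0.10 and the efflux pump gene Abcb1a at -0.27 ± 0.10. Genes of GABA synthesis and signalling were above 0 in 14 of 15 (median 0.065), with Gad1 at 0.16 ± 0.08, and the list of corticosteroid receptors and the CRH, vasopressin and oxytocin systems in 9 of 11 (median 0.069), with Avpr1b at 0.26 ± 0.10. Fancd2osl1 (0.66 ± 0.13), Atp5mk, a gene of the mitochondrial ATP synthase (0.28 ± 0.06), and C1ql3 (0.20 ± 0.05) were the genes with small p on the higher side, and Sox11, an immature neuron gene of the panel, was at -0.34 ± 0.10.

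None of these genes passed in fluoxetine against stress: limma called 0, the smallest adjusted p was 0.400 (Dusp1, Nfkbia and Fancd2osl1), and 541 genes had an unadjusted p under 0.05. Adjusted over the list alone, 3 glucocorticoid-responsive genes (Dusp1, Nfkbia and Ddit4), 2 activity-regulated genes (Dusp1 and Gadd45b) and 0 of the other called lists passed, and of lists not called Sox11 passed among immature neuron genes and Nfkbia among inflammation genes. The groups did not overlap in 10.8% of genes, against 10% by chance. By camera 7 lists passed, and by fry 0. The lists of lower genes were vascular cells (adjusted p = 0.000518, and adjusted p = 0.493 with an estimated correlation), the glucocorticoid-responsive list (0.00114, adjusted p = 0.373 with an estimated correlation), cholesterol synthesis (0.00114, adjusted p = 0.393 with an estimated correlation) and activity (0.00189, adjusted p = 0.479 with an estimated correlation). The lists of higher genes were the CRH, vasopressin and oxytocin list (0.00387, adjusted p = 0.373 with an estimated correlation), GABA (0.00437, adjusted p = 0.393 with an estimated correlation) and olfactory receptors (0.00704, median 0.060, adjusted p = 0.816 with an estimated correlation). The mean of the glucocorticoid-responsive list was -0.121 and its median -0.030, and with equal array medians the median turned to 0.01 while the mean was -0.0811. That setting gave medians of -0.038 for activity and -0.042 for cholesterol synthesis, 0.105 for GABA, 0.108 for the CRH, vasopressin and oxytocin list and 0.1 for olfactory receptors. The nearest of the other 23 lists was that of granule neurons (0.0853). The glucocorticoid-responsive call held with each animal left out. The vascular call ended without stress 1 (mean -0.0838, against -0.154 with all animals, adjusted p = 0.188), the animal with the choroid plexus and meningeal scores of 0.586 and 0.608, and without fluoxetine 1 (adjusted p = 0.0568). Cholesterol synthesis ended without stress 3 (0.058, mean -0.0595 against -0.105) or fluoxetine 2 (0.0507), activity without fluoxetine 2 (0.111, mean -0.0674 against -0.108, and -0.0708 without stress 3), and the CRH, vasopressin and oxytocin list without fluoxetine 2 (0.0948). GABA ended without stress 2 (0.0716, mean 0.0301 against 0.0671, and 0.104 without stress 3) or fluoxetine 1 (0.0568), and olfactory receptors without stress 3 (0.303) or fluoxetine 2 (0.283, mean 0.0296 against 0.0472). Without fluoxetine 2 the count of lists was 4 and without fluoxetine 3 it was 11. Of the panel, 0 of 17 genes passed. With array weights 4 genes passed, Dusp1, Fancd2osl1, Nfkbia and Kcng1, and with all probe sets 1 did.

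Imipramine was compared with stress alone in the same way. Cytosolic ribosomal protein genes were below 0 in 56 of 68 members (median -0.091), with Rps14 at -0.26 ± 0.07, Rpl32 at -0.23 ± 0.07 and Rpl41 at -0.19 ± 0.07. Dusp1 was at 9.17 ± 0.13 against 9.79 ± 0.11 (SD, n = 3), a difference of -0.61 ± 0.11 (SE), and Npas4, an activity-dependent transcription factor gene of neurons, at -0.55 ± 0.12. Pmm1, a phosphomannomutase gene, was at -0.41 ± 0.08 and Iscu, a scaffold for iron-sulphur clusters, at -0.39 ± 0.09. The deubiquitinase genes Usp15 (0.31 ± 0.07) and Usp14 (0.33 ± 0.08), Fancd2osl1 (0.58 ± 0.13) and Lgi1, a secreted synaptic protein gene (0.19 ± 0.05), were higher in value. Bdnf was at 0.25 ± 0.12.

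For imipramine against stress limma called 0 genes, the smallest adjusted p was 0.330 (Dusp1), and 1081 genes had an unadjusted p under 0.05 (357 higher, 724 lower) where chance gives 540.2. The groups did not overlap in 19.7% of genes, and chance gives 10%. None of the ribosomal genes passed when adjusted over the list alone, and of the lists not called Dusp1 and Npas4 passed in the activity list, Dusp1 in the glucocorticoid-responsive list and Cldn5 (-0.30) in the vascular list. By camera 2 lists passed, the ribosomal list (adjusted p = 0.00157, and adjusted p = 0.868 with an estimated correlation) and, higher in value, the olfactory receptors (0.00157, median 0.032, adjusted p = 0.868 with an estimated correlation). The nearest of the other 28 was the interneuron list (0.0764), and fry called 0 lists. With equal array medians the median of the ribosomal list was -0.0465 and that of the olfactory receptors 0.0768. The ribosomal call ended without stress 2 (adjusted p = 0.0503), and that of olfactory receptors without stress 3 (0.0516) or imipramine 1 (0.215, mean 0.0228 against 0.0556, and 0.0847 without imipramine 2). Without stress 1 the count of lists was 4, and it was also 4 without stress 3. It was 8 without the low signal filter, 1 with that filter at the 50th percentile, 7 with equal array medians, 4 with quantile normalisation once more and 1 with the choroid plexus score as a covariate. Of the panel, 0 of 17 genes passed. With array weights 26 genes passed, and with all probe sets 20 did.

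In animals given tianeptine the level of Dusp1 was 9.10 ± 0.08, against 9.79 ± 0.11 in stressed animals (SD, n = 3). The difference was -0.69 ± 0.11 (SE, adjusted p = 0.0891), and other activity-regulated genes were Nr4a1 at -0.44 ± 0.13, Npas4 at -0.41 ± 0.12 and Dusp6 at -0.40 ± 0.12. Dusp1 was at 9.29 ± 0.06 in control, 9.22 ± 0.23 in fluoxetine, 9.17 ± 0.13 in imipramine and 9.495 ± 0.232 in agomelatine animals. All its differences from stress use the same stressed animals, so a high level in these animals alone would give each of them. Heat shock and unfolded protein response genes were below 0 in 18 of 21 members (median -0.12), with the endoplasmic reticulum chaperone genes Hspa5 at -0.28 ± 0.09 and Hsp90b1 at -0.15 ± 0.06 and the transcription factor gene Xbp1 at -0.17 ± 0.06. Oligodendrocyte genes were below 0 in 17 of 17 (median -0.14), with Cnp at -0.16 ± 0.07 and Ermn at -0.18 ± 0.10. Microglia genes were above 0 in 11 of 14 (median 0.15), with Tyrobp at 0.42 ± 0.20 and the complement gene C1qb at 0.30 ± 0.15. Their list scores were 0.248, -0.136 and 0.392 in the 3 animals. Mt1, a metallothionein gene, was at 0.34 ± 0.08, Sp1, a transcription factor gene, at 0.44 ± 0.10, and Ncoa5, a nuclear receptor coactivator gene, at -0.36 ± 0.07.

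None of these genes passed in tianeptine against stress: limma called 0, and 547 had an unadjusted p under 0.05. When adjusted over the list alone, 4 activity-regulated genes passed (Dusp1, Dusp6, Npas4 and Nr4a1) and 0 of the other called lists, while Mt1 and Dusp1 passed in the glucocorticoid-responsive list and Fkbp4 (-0.29) in the CRH, vasopressin and oxytocin list, neither of which was called. The groups did not overlap in 11.2% of genes, against 10% by chance. By camera 5 lists passed. These were stress proteins (lower, adjusted p = 1.08e-05), oligodendrocytes (lower, 0.00306), microglia (higher, 0.00306), activity (lower, 0.0234) and olfactory receptors (higher, 1.08e-05, median 0.066), each with adjusted p = 0.873 with an estimated correlation. The mean of the activity list was -0.103 and its median -0.032, and with equal array medians the median turned to 0.0153 and the mean was -0.0563. That setting also gave medians of -0.0682 for stress proteins, -0.0888 for oligodendrocytes and 0.113 for olfactory receptors. The call of stress proteins held with each animal left out. That of oligodendrocytes ended without stress 1 (mean -0.073, against -0.112 with all animals, adjusted p = 0.306), that of microglia without tianeptine 3 (0.0225 against 0.134, adjusted p = 0.475, with 0.0765 without stress 2 and 0.286 without tianeptine 2), and that of activity without stress 1 (adjusted p = 0.126), stress 3 (0.136, mean -0.0664) or tianeptine 3 (0.174). Olfactory receptors ended without tianeptine 2 (0.0663, mean 0.0444 against 0.0753, with 0.0408 without tianeptine 1 and 0.141 without tianeptine 3). The nearest of the other 25 lists was inflammation (0.0583), and fry called 0 lists. Of the panel, 0 of 17 genes passed. Fitted without the agomelatine animals 1 gene passed, Dusp1 (adjusted p = 0.025), as it did with array weights (0.0186) and in a fit on these 2 groups alone (0.0457), and with all probe sets 26 did. The count of lists was 3 with the low signal filter at the 50th percentile, 9 with the array difference as a covariate and 3 with the oligodendrocyte score as a covariate.

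**Figure D2:**
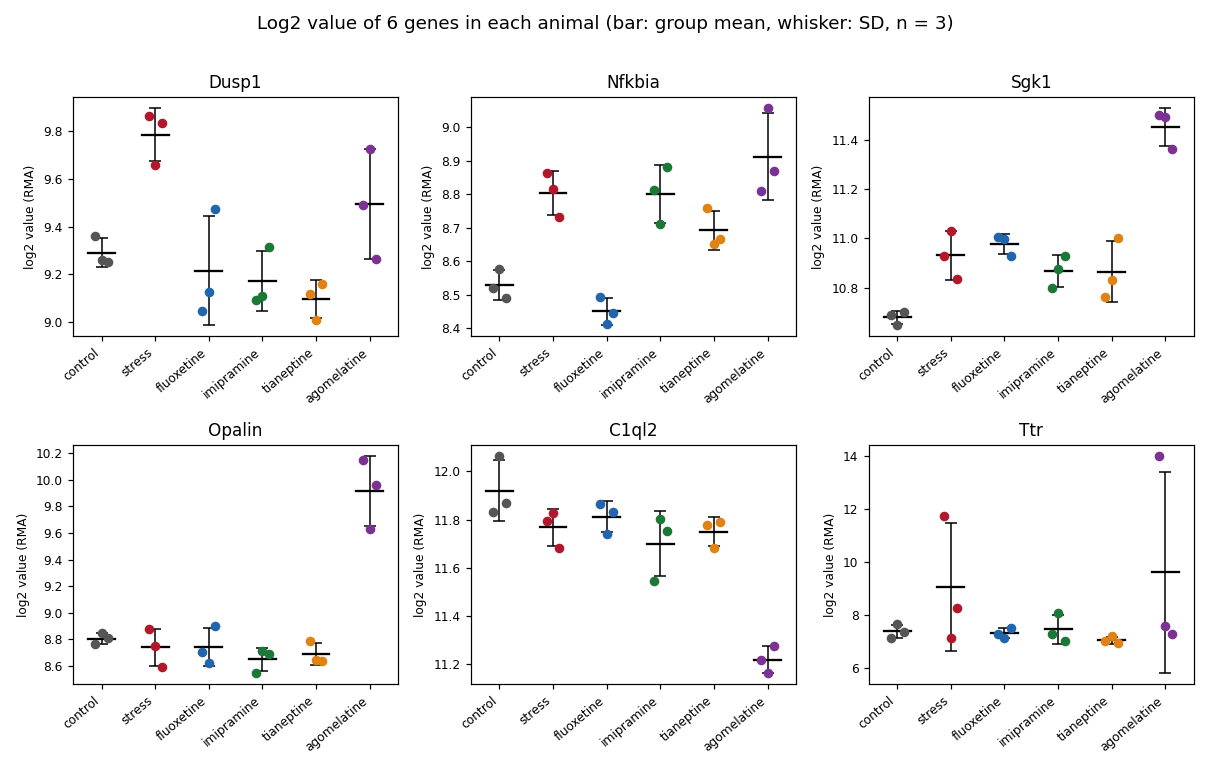
Each point is 1 animal's RMA log2 value of the gene named above the panel, by group, with the group mean (bar) and SD (whisker, n = 3). Dusp1 lies at 9.66 to 9.86 in the stressed animals, Opalin at 9.63 to 10.15 in the agomelatine animals and no higher than 8.90 elsewhere, and Ttr at 14.01 in agomelatine 1.

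Myelin genes rose in animals given agomelatine compared with stress alone. Opalin, a protein of oligodendrocyte membranes, rose from 8.74 ± 0.14 to 9.91 ± 0.26 (SD, n = 3), a difference of 1.18 ± 0.11 (SE, adjusted p = 1.11e-05). Ermn rose by 0.82 ± 0.10, Mog by 0.65 ± 0.08, Mal by 0.67 ± 0.14, Fa2h, a hydroxylase of myelin lipids, by 0.67 ± 0.13, and the myelin basic protein gene Mbp by 0.48 ± 0.08. Of 17 oligodendrocyte genes 13 rose, 0 fell and 4 did not pass. Of 8 genes of the pyramidal neurons of the neighbouring CA fields 4 rose, namely Meis2 (1.38 ± 0.20), Neurod6 (0.77 ± 0.19), Wfs1 (0.76 ± 0.20) and Nectin3 (0.60 ± 0.11). Of 5 granule neuron genes C1ql2, which encodes a secreted synaptic protein, fell by 0.55 ± 0.07 (adjusted p = 0.000254), and Prox1, the transcription factor of granule neuron identity, was at -0.24 ± 0.09 (adjusted p = 0.0915). Of 12 astrocyte genes 2 fell, the receptor gene Ntsr2 (-0.33 ± 0.08) and Aldh1l1 (-0.24 ± 0.06).

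Other genes changed between agomelatine and stress animals as well. Sfrp2, a modulator of Wnt signalling, rose by 1.16 ± 0.14, Dusp5, a phosphatase of ERK, by 0.75 ± 0.12, Socs2, an inhibitor of cytokine signalling, by 0.72 ± 0.14, and Sgk1 by 0.52 ± 0.07 (11.45 ± 0.08 against 10.93 ± 0.10, adjusted p = 0.000202). Rpl39 rose by 0.68 ± 0.06 (adjusted p = 5.01e-06), and it was also the gene that differed by 0.73 between repeat and first arrays. The opioid peptide genes Penk (-0.80 ± 0.13) and Pdyn (-0.70 ± 0.12), the transcription factor gene Nhlh1 (-0.94 ± 0.16), the complement regulator gene Cd55 (-0.75 ± 0.17), the small GTPase gene Rasl10a (-0.65 ± 0.08), and Slc30a3, the vesicular zinc transporter gene (-0.61 ± 0.07), fell. In the panel of 17, Sgk1 and Mbp rose and the serotonin 1A receptor gene Htr1a fell (-0.40 ± 0.09, adjusted p = 0.0119). Bdnf was at 0.04 ± 0.12. Ttr was at 14.01 in agomelatine 1 and at 7.58 and 7.29 in the other 2, the choroid plexus score was 2.77 in agomelatine 1 and -0.1 and -0.146 in the others, and the meningeal score was 0.654, 0.297 and -0.174.

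In agomelatine against stress limma called 1163 of 10804 genes, 452 higher and 711 lower. The median size was 0.31 on the log2 scale, 36 of the genes changed by more than 1.5-fold, and 25.2% of genes did not overlap between the groups, where chance gives 10%. With the deposited values 38.9% of the calls were higher. Quantile normalisation once more gave 638 higher and 642 lower, and equal array medians 811 higher and 423 lower. Without stress 2 the count was 573 and without stress 3 it was 652. The call ended for Htr1a without agomelatine 1 (adjusted p = 0.054), for Neurod6 without stress 1 (0.0614), and for Wfs1 without stress 1 (0.0779), stress 2 (0.0963), agomelatine 1 (0.0717) or agomelatine 2 (0.0949). It also ended for Ntsr2 without stress 3 (0.0872) or agomelatine 3 (0.0553), and for Aldh1l1 without stress 2 (0.0676), stress 3 (0.0604) or agomelatine 3 (0.0564). With each animal's position along the repeat-array difference as a covariate the count was 132, with the oligodendrocyte score as a covariate it was 7, and in a fit on these 2 groups alone it was 163. It was 704 with the random block, 637 with array weights, 1879 with all probe sets and 1957 at an adjusted p under 0.1. Because the oligodendrocyte score separates the agomelatine from the stressed animals, the count of 7 with that covariate does not show that oligodendrocyte content explains these genes.

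By camera 5 lists passed in agomelatine against stress. Oligodendrocyte genes had a median of 0.48 (adjusted p = 3.61e-16, and adjusted p = 0.129 with an estimated correlation), pyramidal neuron genes 0.48 (0.00115, adjusted p = 0.544 with an estimated correlation) and granule neuron genes -0.19 (0.0425, adjusted p = 0.597 with an estimated correlation), and fry also called these 3. Astrocyte genes had a median of -0.18 (0.0119, adjusted p = 0.952 with an estimated correlation), and choroid plexus genes 0.79 (0.0119, adjusted p = 0.952 with an estimated correlation), with 0 of 8 members passing singly. Adjusted over the list alone, 16 oligodendrocyte genes were higher and 1, Gpr17, lower (-0.21), 5 pyramidal genes were higher, 2 granule neuron and 5 astrocyte genes lower, and 0 choroid plexus genes passed. The nearest of the other 25 lists was cholesterol synthesis (0.119). The oligodendrocyte and pyramidal calls held with each animal left out. Choroid plexus ended without agomelatine 1 (mean -0.211, against 0.752 with all animals, adjusted p = 0.961, with 1.22 without agomelatine 2 and 1.25 without agomelatine 3), astrocytes without agomelatine 3 (-0.0862 against -0.165, adjusted p = 0.199), and granule neurons without stress 1 (adjusted p = 0.222), stress 2 (0.0752), agomelatine 1 (0.209) or agomelatine 2 (0.163). Without agomelatine 1 the count of lists was 3 and without stress 3 it was 8. It was 1 with the low signal filter at the 50th percentile, 12 with the array difference as a covariate and 3 with the choroid plexus score as a covariate.

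**Figure D3:**
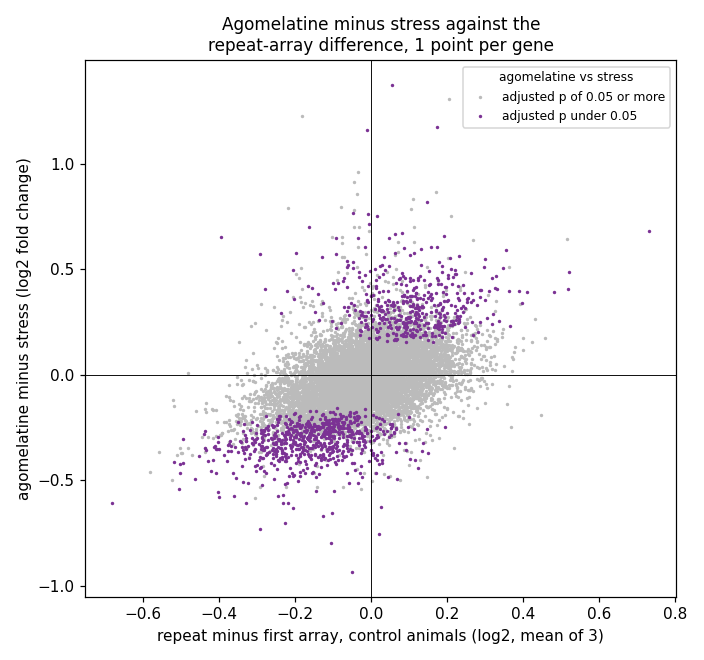
Each point is 1 of 10804 genes, placed by its mean repeat minus first array difference in the 3 control animals (x, log2) and its agomelatine minus stress difference (y, log2), with the 1163 called genes in purple. The 2 differences share no arrays and correlate with r = 0.476 across genes.

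Against untreated animals, agomelatine again had the most called genes, 1036 (570 higher, 466 lower). Meis2 rose by 1.66 ± 0.20, Sgk1 by 0.77 ± 0.07 (adjusted p = 6.05e-06), Mbp by 0.52 ± 0.08 and the activity-regulated genes Nr4a1, Nr4a2 and Homer1 by 0.62 ± 0.13, 0.57 ± 0.13 and 0.48 ± 0.11. Cholesterol synthesis genes had 5 of 17 that rose, among them Idi1 (0.72 ± 0.15) and Insig1, a regulator of that pathway (0.47 ± 0.10), and C1ql2 (-0.70 ± 0.07), Prox1 (-0.44 ± 0.09) and Rasl10a (-0.78 ± 0.08) fell. The calls of Nr4a2 and Homer1 ended without control 1 (adjusted p = 0.0617) and control 2 (0.0658). Enpp2 rose by 1.52 ± 0.43 and the serotonin receptor gene Htr2c by 2.39 ± 0.73, with levels of 13.31, 10.62 and 10.68 and of 11.86, 9.49 and 7.31 in the 3 agomelatine animals. Agomelatine 1 had a choroid plexus score of 2.77, against -0.1 and -0.146 in the other agomelatine animals. Htr2c was at 8.32 ± 1.42 (SD, n = 3) in stressed animals, so its level also varied widely there. Without agomelatine 1 the difference of Enpp2 was 0.63 ± 0.15 (adjusted p = 0.0222) and that of Htr2c 1.23 ± 0.57 (0.226). The call of Enpp2 ended without control 1 (0.0998), control 2 (0.105) or control 3 (0.0655), and that of Htr2c also without agomelatine 2 (0.0739), control 1 (0.118), control 2 (0.148) or control 3 (0.077). The 7 called lists were oligodendrocytes (higher, 7.21e-19, adjusted p = 0.0764 with an estimated correlation), pyramidal neurons (higher, 0.000107, adjusted p = 0.221 with an estimated correlation), granule neurons (lower, 0.00404, adjusted p = 0.221 with an estimated correlation), choroid plexus (higher, 0.00404), cholesterol synthesis (higher, 0.00406, adjusted p = 0.701 with an estimated correlation), activity (higher, 0.0426) and olfactory receptors (lower, 0.000287). The choroid plexus, activity and olfactory receptor lists had adjusted p = 0.775 with an estimated correlation. The choroid plexus call ended without agomelatine 1 (mean 0.0791 against 1.04, adjusted p = 0.553), as did that of olfactory receptors (-0.0701 against -0.137, adjusted p = 0.319, with a mean of -0.0894 under quantile normalisation once more), and activity ended without agomelatine 2 (0.135), control 1 (0.0708) or control 2 (0.0914). Adjusted over the list alone, 16 oligodendrocyte, 5 pyramidal, 5 activity-regulated, 6 cholesterol and 1 choroid plexus genes were higher, 3 granule neuron genes lower, and 0 olfactory receptor genes passed, of which 3 fell among all genes. Quantile normalisation once more gave 586 higher and 635 lower calls. The count of genes was 523 without agomelatine 1, 561 without control 1, 278 without control 2, 1864 with the first arrays of the controls alone and 670 with the repeat arrays alone. It was 526 with array weights, 322 in a fit on the 2 groups, 521 and 0 with the choroid plexus and oligodendrocyte scores as covariates, and 1716 at an adjusted p under 0.1. The count of 0 again comes from a covariate that separates the agomelatine animals from the others.

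Imipramine animals had 2 genes that fell against control, Rpl39 (-0.36 ± 0.06) and H1f4 (-0.36 ± 0.05), both at an adjusted p of 0.0314, with 894 genes at an unadjusted p under 0.05. These are the genes that were higher by 0.73 and 0.52 on the repeat arrays of the controls. Against the first arrays alone the differences were 0.0060 ± 0.06 and -0.10 ± 0.06 (adjusted p = 0.988 and 0.681), and against the repeat arrays alone -0.73 ± 0.06 and -0.62 ± 0.05. Both calls ended with the first arrays of the controls alone, with equal array medians, with the replicate number as a block, and without imipramine 1, 2 or 3, control 1 or control 2 (0 genes in each). The count was also 0 with the random block, with all probe sets and without a variance trend. Without control 3 the count was 2, of which 1 was shared, with the array difference as a covariate it was 1, in a fit on the 2 groups 5, with array weights 99 and with the repeat arrays alone 187. Asb3 was at 0.38 ± 0.07 (adjusted p = 0.0762), and the ribosomal list lay lower (0.000106, median -0.065, adjusted p = 0.942 with an estimated correlation, mean -0.0706 and -0.0418 without control 2), with 1 gene that fell and 3 lower when adjusted over the list alone. For fluoxetine against control limma called 0 genes (528 at an unadjusted p under 0.05), with Sgk1 at 0.30 ± 0.07 and Ptma at -0.22 ± 0.05, both at 0.629, and 79 genes passed with the repeat arrays alone and 25 with array weights. The lists called for fluoxetine were GABA (higher, 0.00214), interneurons (higher, 0.00156) and vascular cells (lower, 7.54e-06), each with adjusted p = 0.57 with an estimated correlation, and lysosomal genes (higher, 0.0417, adjusted p = 0.95 with an estimated correlation). GABA and interneurons ended without control 2 (adjusted p = 0.0881 and 0.109), and lysosomal genes without control 2 (0.0662), control 3 (0.195) or fluoxetine 3 (0.294). For tianeptine it called 0 (436 at an unadjusted p under 0.05), with Mt1 at 0.47 ± 0.08 (0.0634), a gene that passed without control 1, and 60 genes passed with the repeat arrays alone. The lists called for tianeptine were the glucocorticoid-responsive genes (higher, 0.0283), stress proteins (lower, 0.00469) and microglia (higher, 0.00469), each with adjusted p = 0.899 with an estimated correlation, and 1 glucocorticoid-responsive gene passed when adjusted over the list alone. The glucocorticoid-responsive call ended without tianeptine 2 (adjusted p = 0.066) or tianeptine 3 (0.181, mean 0.0501 against 0.0759), stress proteins without tianeptine 1 (0.187) or control 3 (0.137, mean -0.0382 against -0.0618), and microglia without tianeptine 1 (0.0519) or tianeptine 3 (0.293, mean 0.0833 against 0.195, with 0.347 without tianeptine 2).

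Compared directly, agomelatine differed from each other drug and those drugs did not differ from each other in any gene called. Oligodendrocyte genes were lower with fluoxetine, imipramine and tianeptine than with agomelatine, where 13, 16 and 15 of 17 members fell (14, 16 and 16 adjusted over the list alone) and the list means were -0.516, -0.579 and -0.6. The camera adjusted p of this list was 7.91e-16, 4.43e-19 and 3.3e-18 (adjusted p = 0.138, 0.0735 and 0.0865 with an estimated correlation). Opalin differed by -1.26 ± 0.11 for imipramine and -1.22 ± 0.11 for tianeptine, Meis2 by -1.63 ± 0.20 for fluoxetine, Penk by 0.91 ± 0.13 for imipramine and 0.77 ± 0.13 for tianeptine, and Pdyn by 0.84 ± 0.12 for fluoxetine. limma called 1273 genes for fluoxetine against agomelatine (725 higher, 548 lower), 1014 for imipramine (470 higher, 544 lower) and 1457 for tianeptine (754 higher, 703 lower). Agomelatine was given at 40 mg/kg and the others at 10 mg/kg, in different vehicles. For fluoxetine, imipramine and tianeptine the counts were 175, 503 and 535 in fits on the 2 groups, 830, 660 and 791 with the choroid plexus score and 1, 0 and 0 with the oligodendrocyte score as a covariate, and 2020, 1681 and 2218 at an adjusted p under 0.1. With the array difference as a covariate they were 468 for fluoxetine and 845 for tianeptine, with array weights 829 and 720, for imipramine 675 with the random block, and with all probe sets 1661 for imipramine and 2223 for tianeptine. Without fluoxetine 2 the count for fluoxetine was 826. For imipramine it was 649 without agomelatine 1 and 533, 453 and 522 without imipramine 1, 2 and 3. For tianeptine it was 855 without agomelatine 1, 736 without tianeptine 1 and 874 without tianeptine 2. Since the oligodendrocyte score separates the agomelatine animals from the others, the low counts with that covariate show no cause.

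Imipramine and tianeptine share a fused 3-ring core with a side chain that carries an amine, tianeptine's ending in a carboxylic acid, and were given at the same dose. The complement gene C3 had a level of 8.14 ± 0.08 with imipramine and 9.09 ± 0.26 with tianeptine (SD, n = 3), a difference of -0.95 ± 0.19 (SE), with Stat5a at -0.38 ± 0.08 and Mt1 at -0.34 ± 0.08, all at an adjusted p of 0.789. limma called 0 genes, with 664 at an unadjusted p under 0.05. The 95% interval of a gene's difference had a median half-width of 0.17 on the log2 scale, and in 10639 genes (98.5%) it lay within 1.5-fold in both directions. By camera microglia genes were lower with imipramine (adjusted p = 1.01e-05, median -0.28), as were ribosomal genes (0.00269), and stress proteins were higher (0.00269), each with adjusted p = 0.946 with an estimated correlation, and 7 microglia genes were lower when adjusted over the list alone. The mean of the microglia list, -0.298, was -0.45 without tianeptine 2 and -0.186 without tianeptine 3, with the call held. The ribosomal call ended without imipramine 2 (adjusted p = 0.0834), imipramine 3 (0.0543) or tianeptine 3 (0.472, mean -0.0225 against -0.0693, with -0.11 without tianeptine 2), and that of stress proteins without imipramine 1 (0.0897) or tianeptine 1 (0.0582). Fluoxetine against imipramine gave 0 called genes and 1191 at an unadjusted p under 0.05, with the neuropeptide gene Npy at 0.54 ± 0.12 (0.326) and 6 called lists. Without fluoxetine 3 the count of genes was 1, and with array weights, which gave fluoxetine 3 the lowest weight (0.308), it was 486. Fluoxetine against tianeptine gave 0 and 481, with C3 at -0.86 ± 0.19 (0.998) and 8 called lists. Each of these 6 and 8 calls ended without some animal. In both the smallest list p with an estimated correlation was above 0.6 (0.681 and 0.671).

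Effects of stress and of each drug were set against each other across the 10804 genes. The correlation of stress against control with drug against stress was -0.575 for fluoxetine, -0.506 for imipramine, -0.594 for tianeptine and -0.195 for agomelatine. The stressed animals enter both sides, and simulated groups without any effect gave -0.47 (-0.867 to 0.148). The covariances were -0.00605, -0.006, -0.0062 and -0.00355, against -0.00508 in the simulation (-0.0154 to 0.00116), so none lay outside what the shared animals give. For agomelatine the correlation was 0.1048 with the first arrays of the controls alone. Between drugs the correlations were 0.406 (fluoxetine and imipramine), 0.568 (fluoxetine and tianeptine), 0.556 (imipramine and tianeptine), 0.147 (fluoxetine and agomelatine), 0.254 (imipramine and agomelatine) and 0.106 (tianeptine and agomelatine). The simulated value was 0.47 (-0.148 to 0.867), and the covariances, 0.00184 to 0.00627, lay within the simulated range around 0.00508. Groups of 3 stressed animals leave too few for splitting them, so part of any such correlation may come from the shared animals. Genes are not independent replicates.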

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

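The splits of the animals were planned before the result was seen, and all other tests of explanations in this part were chosen only after the result was seen. For 2 explanations, the array difference as the whole cause of the genes outside 3 lists in the first pattern and a stress group that lies high by chance, the bound was made wider after a first value was known, and both are left open. The tests of an array shift in the first and the third pattern were divided into parts, and that of white matter made stricter, after their values were known.

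Fluoxetine, imipramine and tianeptine each differed from agomelatine by a direct test, in 1273, 1014 and 1457 genes. Gene lists that differed by camera and by fry, adjusted over 180 tests of drug pairs, were oligodendrocytes (mean log2 differences of -0.516, -0.579 and -0.6 for fluoxetine, imipramine and tianeptine minus agomelatine), pyramidal neurons (-0.577, -0.488 and -0.504), granule neurons (0.329, 0.29 and 0.282) and, for fluoxetine, cholesterol synthesis (-0.191). With an estimated correlation 0 of the 180 passed, and adjusted within its own comparison the granule neuron call of tianeptine minus agomelatine ended without agomelatine 2 (adjusted p = 0.0607). Among probe sets without a gene name here, which the comparisons of genes do not use, 762 of 9104 differed between agomelatine and stress animals (438 higher, 324 lower).

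The first pattern is the set of genes that differed between agomelatine and stress animals. A lower share of granule neurons with the other cell types alike is argued against by the lists, since oligodendrocyte genes moved apart from astrocyte genes by 0.653 (SD 0.143). A shift like that between the repeat and first control arrays may account for part of it. Of the 1150 called genes outside the oligodendrocyte list, 89% differed between repeat and first control arrays in the direction of their agomelatine difference, against 67.7% of all genes. Shifts of another kind were not measured, since the round of each array is not given. The pyramidal and granule neuron lists differed by -0.00917 (SD 0.0375) and 0.0022 (SD 0.0231) between repeat and first arrays. Between agomelatine and stress they differed by 0.491 and -0.238, which argues against a shift like that of the repeat arrays for them, as for the oligodendrocyte list below. As the whole cause for the 1145 called genes outside these 3 lists it cannot be told apart from the group, because the agomelatine animals lie at 3.75 to 6.59 along that axis and the stressed ones below 0: with the axis as a covariate their median signed difference was 0.286 (median SE 0.139), against 0.305 before (0.0754); over all genes 132 were called, 67 shared and 65 not called before, and in the 1096 whose call ended the median went from 0.302 (SE 0.0753) to 0.277 (SE 0.139). More white matter and CA tissue in the agomelatine samples stays open too, with 88% of 25 oligodendrocyte and pyramidal genes above 0 but pyramidal and granule scores of agomelatine 3 (0.162 and -0.0897) inside the range of stressed animals (up to 0.177, down to -0.101), as do an effect of the drug, its dose of 40 mg/kg, its vehicle and the injections, which were not tested.

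The second pattern is the higher oligodendrocyte list in agomelatine animals, 0.488 above stress. The repeat arrays differed from the first by -0.0399 in this list (SD 0.0432, n = 3), which argues against a shift of the kind seen between these arrays as its source. Another kind of shift between arrays was not tested, since the round of each array is not given. More white matter in the samples and an effect of the drug, dose, vehicle or injections remain open, and no test here separates them.

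The third pattern is the glucocorticoid-responsive list, higher in stress than in control animals and lower with fluoxetine than with stress alone. A single stressed animal as the source is argued against by the list means. With each stressed animal left out they were 0.123 to 0.142 in stress against control and -0.111 to -0.13 in fluoxetine against stress. The highest camera adjusted p was 0.0246 with the preset correlation. With an estimated one the list was called in neither comparison, and fry called 0 lists in both. Camera with the preset correlation called at least as many lists in 8 and 5 of the 10 splits of these animals. It also called the olfactory receptors, so its p-values decide little here. A shift along the axis between repeat and first arrays as the whole cause is argued against for fluoxetine. Its animals overlap with stressed ones along that axis, and with the axis as a covariate the list mean was -0.12, against -0.121 before (camera adjusted p = 0.000378). For stress such a shift cannot be told apart from the group: control and stressed animals lie apart along the axis, so that 0.000242 and a mean of 0.13 decide nothing. The list differed by -0.0592 between repeat and first arrays (SD 0.0344), with means of 0.104 against the first and 0.163 against the repeat arrays. Shifts of another kind were not measured. A stress group that lies high by chance may also produce both differences and cannot be told apart from an effect: the mean of the 4 drug minus control differences was 0.0599 (SD 0.0326), between 0 and the stress difference. An effect of stress, of fluoxetine or of its injections stays open, untested beyond these comparisons.

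Other splits of the 18 animals were counted for the F test: 1 of 100 splits, the real one, gave as many genes (730, highest other 371). That makes chance unlikely as the source of the whole count but does not exclude it. How much of the count comes from the agomelatine animals is not known, since the F test was not run without that group. For 2 groups of 3 the 10 splits are too few for a share under 0.05. For genes the real value and the highest other were 0 and 0 for stress against control, 0 and 3 for fluoxetine, 0 and 0 for imipramine, 0 and 0 for tianeptine and 1163 and 51 for agomelatine against stress. Against control they were 0 and 0 for fluoxetine, 2 and 0 for imipramine, 0 and 1 for tianeptine and 1036 and 1 for agomelatine. Between drugs they were 0 and 0 (fluoxetine and imipramine), 0 and 16 (fluoxetine and tianeptine), 1273 and 22 (fluoxetine and agomelatine), 0 and 0 (imipramine and tianeptine), 1014 and 2 (imipramine and agomelatine) and 1457 and 0 (tianeptine and agomelatine). For lists they were 5 and 6 for stress, 7 and 9 for fluoxetine, 2 and 7 for imipramine, 5 and 8 for tianeptine and 5 and 10 for agomelatine, so in each of these comparisons another split called more lists than the real one. Of the 10 splits, 8, 5, 7, 8 and 10 called at least as many lists. The repeat arrays allow 4 splits, all 4 with 0 genes.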

How the results depend on the processing

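Leaving out the agomelatine group and the covariates from the choroid plexus and oligodendrocyte scores were chosen after seeing the data, the other alternatives before. The counts of 0 genes in stress against control and in fluoxetine, imipramine and tianeptine against stress stayed at 0 with each animal left out. Where a value below changed, the cause was not tested. The number of arrays and the signal over background limit all of these values, since RMA values of dim probe sets are compressed.

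With the first arrays of the controls alone, 0 genes changed in imipramine and 1864 in agomelatine against control, and the correlation of stress and agomelatine effects turned to 0.1048. With the repeat arrays alone, 126 genes (101 higher) and 1 list changed in stress against control, and 79, 187, 60 and 670 genes in fluoxetine, imipramine, tianeptine and agomelatine against control. With all 21 arrays and animal as a random block (correlation 0.16), 704 genes changed in agomelatine against stress, 0 in imipramine and 1 in tianeptine against control, 675 between imipramine and agomelatine, and 486 differed among the 6 groups.

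Without the low signal filter 8 lists changed in imipramine against stress. With it at the 50th percentile 1 gene changed in tianeptine against control, 821 between repeat and first arrays, and 1, 1, 3 and 1 lists in stress against control and in imipramine, tianeptine and agomelatine against stress. With all probe sets, a larger number of tests, 1, 20, 26 and 1879 changed in fluoxetine, imipramine, tianeptine and agomelatine against stress, 0 in imipramine and 1 in tianeptine against control, 1661 between imipramine and agomelatine, 2223 between tianeptine and agomelatine, and 1127 differed among the groups. Of the calls in the fluoxetine, imipramine and tianeptine comparisons with stress, 1, 20 and 25 were unnamed here. Quantile normalisation once more gave 4 lists in imipramine against stress. Equal medians gave 7 lists there and 0 genes in imipramine against control, which also had 0 without a trend. A robust prior gave 1 gene in tianeptine against control.

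Array weights (0.308 for fluoxetine 3 to 2.85 for imipramine 3) gave 4, 26, 1 and 637 genes in fluoxetine, imipramine, tianeptine and agomelatine against stress, 25, 99, 1 and 526 in the same drugs against control, 486 between fluoxetine and imipramine, 829 between fluoxetine and agomelatine and 720 between tianeptine and agomelatine. With the replicate number as a block 0 genes changed in imipramine against control, and no other count moved by over 1.5 times (1067 genes in agomelatine against stress, for example). The numbers met no bound for pairing: in 0 of 15 comparisons were all correlations of same-numbered animals over 0.1 (-0.3 to 0.292). They ran from 0.0629 to 0.29 in imipramine against control and from 0.069 to 0.292 in tianeptine against stress, so pairing is not excluded there.

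With the array difference as a covariate 132 genes and 12 lists changed in agomelatine and 9 lists in tianeptine against stress, 1 gene in imipramine against control, 468 between fluoxetine and agomelatine and 845 between tianeptine and agomelatine, and 227 differed among the groups. At an adjusted p under 0.1, 1 and 1957 genes changed in tianeptine and agomelatine against stress, 1 and 1716 against control, 2020, 1681 and 2218 between fluoxetine, imipramine and tianeptine and agomelatine, and 1271 among the groups. Fits on the 2 groups compared have fewer animals for the spread and do not share it with the other groups, which spread less than the agomelatine group. In these fits 1 and 163 changed in tianeptine and agomelatine against stress, 5 and 322 in imipramine and agomelatine against control, 175, 503 and 535 between fluoxetine, imipramine and tianeptine and agomelatine, and 1 between imipramine and tianeptine. Camera with an estimated correlation called 0 lists in all 5 comparisons with stress or of stress, and fry 0 in stress, fluoxetine, imipramine and tianeptine and 3 in agomelatine. Against control fry called 0 lists for fluoxetine, imipramine and tianeptine and 3 for agomelatine. Between drugs it called 5, 3 and 3 lists for fluoxetine, imipramine and tianeptine against agomelatine and 0 in each pair without agomelatine.

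Without the agomelatine group 1 gene changed in tianeptine against stress. With the choroid plexus score as a covariate 521 changed in agomelatine against control, 830, 660 and 791 between fluoxetine, imipramine and tianeptine and agomelatine, 261 differed among the groups, and 1 and 3 lists changed in imipramine and agomelatine against stress. With the oligodendrocyte score as a covariate, which itself separates the agomelatine animals from the others, 7 genes changed in agomelatine against stress, 0 against control, 1, 0 and 0 between fluoxetine, imipramine and tianeptine and agomelatine, 1 between fluoxetine and tianeptine, 0 differed among the groups, and 3 lists changed in tianeptine against stress. Fa2h turned to -0.22 (adjusted p = 0.641) and Mal to -0.12 (0.850) there.

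With 1 animal left out, 573 to 1164 genes changed in agomelatine against stress, 278 to 1250 in agomelatine, 0 to 2 in imipramine and 0 to 1 in tianeptine against control, 826 to 1416, 453 to 1300 and 736 to 1565 between fluoxetine, imipramine and tianeptine and agomelatine, 0 to 1 between fluoxetine and imipramine, and 251 to 1036 among the groups. Lists ran from 2 to 7, 4 to 11, 2 to 4, 4 to 7 and 3 to 8 in the stress, fluoxetine, imipramine, tianeptine and agomelatine comparisons. Of 34 named genes called in agomelatine against stress, 707 values under 21 alternatives included 615 that kept their call and direction, 90 that lost the call and 2 that turned. Among named genes not called, 12 of 1059 values in stress against control, 4 of 1254 in fluoxetine, 16 of 957 in imipramine, 3 of 1172 in tianeptine and 16 of 454 in agomelatine against stress passed, and 24, 8, 14, 9 and 39 of the same values had the other sign. The random block and the robust prior were not run for lists.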

Other observations

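The genes below were picked after their values were seen, from lists that were fixed but not called in agomelatine against stress. Of the 1150 called genes outside the oligodendrocyte list in that comparison, 89% differed in the same direction between repeat and first control arrays. With the array difference as a covariate 67 of the 1163 called genes kept their call and direction. For most genes below no value with 1 animal left out is given here. Among receptors for monoamines, Adra2c, an alpha-2 adrenergic receptor gene, fell by 0.42 ± 0.10 (SE, 3 animals per group, limma adjusted p = 0.0124) and Htr4, a serotonin receptor gene, fell by 0.31 ± 0.08, beside Htr1a at -0.40 ± 0.09. Maoa, the monoamine-degrading oxidase gene, rose by 0.19 ± 0.06. Adjusted over the list alone, 2 genes of that list were higher and 4 lower, and camera gave 0.843. Genes of glucocorticoid response moved both ways, with Cdkn1a, a cell cycle inhibitor gene, up by 0.48 ± 0.14 beside Sgk1, and Mt1 (-0.38 ± 0.08), Arrdc2 (-0.32 ± 0.08) and Ddit4 (-0.27 ± 0.08) down (camera 0.801).

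The 47 genes of mitochondrial respiration included 6 that rose, among them the complex I genes Ndufs5 (0.47 ± 0.08), Ndufa6 (0.39 ± 0.10) and Ndufb6 (0.38 ± 0.10), and 1 that fell, the complex II gene Sdhc (-0.34 ± 0.09, camera 0.272). The 68 ribosomal protein genes included 6 that rose, such as Rpl22l1 (0.50 ± 0.14) and Rpl41 (0.36 ± 0.07), and 3 that fell, Rpl36a (-0.44 ± 0.10), Rpl28 (-0.31 ± 0.06) and Rps2 (-0.25 ± 0.04, camera 0.398). Over all genes 1163 of 10804 were called, so lists of this size hold some called members in any case. Many ribosomal protein genes have near-identical copies, so these values are uncertain where probes are shared. Synaptic genes that rose were Homer1 (0.46 ± 0.11), Nlgn1 (0.19 ± 0.05) and Syt1 (0.15 ± 0.04, camera 0.344), Gabra5, a GABA-A receptor subunit gene, rose by 0.47 ± 0.10, and Slc1a1, a neuronal glutamate transporter gene, fell by 0.36 ± 0.05.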
